A study of Mus musculus with 6 samples.

How the data were processed

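The series holds single-cell RNA measurements of 6 libraries from mouse tumours, 3 of sedentary and 3 of exercised male C57Bl/6 mice. The tumours were grown from YUMMER1.7 cells, a mouse melanoma line made more visible to the immune system by ultraviolet irradiation of its parent line. Per the labels, 600000 cells were injected under the skin, and mice of the exercise group ran at 12 metres per minute for 45 minutes a day on 14 days. Whole tumours were minced, digested with collagenase and DNase for 15 minutes at 37 degrees, passed through a 100 micrometre strainer and freed of red cells, and all suspensions had a viability above 70%. Libraries were made with the 10x Genomics 3' version 3 chemistry, which tags each captured RNA molecule with a unique molecular identifier (UMI) at its 3' end. No cell type was sorted, so each library holds tumour, immune and stromal cells. Digestion at 37 degrees can switch on immediate early and heat shock genes, and a list of each was tested for that reason.

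The authors deposited, for each library, a matrix of raw UMI counts per gene and cell barcode, with no normalised values. Per the submitters' processing notes, reads were processed with Cell Ranger 6.1.2 against the mouse build mm10 (GRCm38). Per the file headers, the matrices were written by software version 3.1.0. Both versions are given here because the files do not settle which one made the counts. The choice of version can change which reads are counted and which barcodes are called cells. The barcodes had already been called as cells, so empty droplets could not be used to estimate free RNA, and no correction for free RNA was made. The matrices list 31053 genes, of which 30934 were found by identifier in the GENCODE M21 annotation of GRCm38 and 119 were not. Gene positions were taken from that annotation.

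The 6 libraries held 58351 barcodes, between 8115 and 10913 each, with between 97426009 and 131778565 UMIs per library. Barcodes with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 52390. The mitochondrial limit removed 5871 barcodes, 7.58% to 11.8% of a library, and 1756 had too few genes. Scrublet, run within scanpy 1.11.5, called 984 of the remaining cells doublets, which were removed. It called 1.14% to 2.74% per library, fewer than the 5.76% to 8.06% expected at 0.8% per 1000 barcodes that passed these limits (the number of cells loaded is not given), so doublets remain among the 51406 cells kept. Kept cells of a library had a median of 5902 to 12426.5 UMIs and 2000 to 3243 genes. Counts of each cell were scaled to a common total and log transformed for clustering only, with 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0), seed 1.

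This gave 29 clusters over all libraries. T and NK-like, B-like and stromal clusters were clustered again with 1000 variable genes, at resolution 1 for T and NK-like cells and 0.5 for the others. A cluster was named from 19 lists of marker genes when at least 3 markers of a list were raised in it over other clusters. Sub-clusters were named from the markers they expressed, not from those raised over sister sub-clusters. A count made after naming, against the clusters of all other cells, found 6 or 7 CD8 T markers raised in each CD8 T-like sub-cluster and 11 fibroblast markers in both fibroblast-like ones, 1 of which also had 4 pericyte markers. Unnamed T sub-clusters, with mixed subset markers, few UMIs or genes of other cells, had 5 or 6 CD8 T markers raised, so that count does not set the named ones apart. Against sister sub-clusters only sub-cluster 2 of the CD8 T-like cells had at least 3 CD8 T markers raised. The 10 genes with the largest fold over other cells were compared with the same lists. Names carry the ending "-like" because they rest on RNA alone. A large population, made of 8 clusters, was to be called tumour-like. It expressed Cspg4, Cdh2 and Nes but almost no pigment cell genes, with 7 UMIs of Mlana, 5 of Tyr, 9 of Dct and 2 of Sox10 among 610193096. Pmel had 163 UMIs, and Mitf, with 6044, was the exception. Its Col1a1 level of 8.69 CPM lay far below the 13080 CPM of fibroblast-like cells, the largest gap of the genes compared. Other genes set the 2 less apart, with Col3a1 at 943.8 and 19020 CPM, Pdgfra at 142.8 and 346.8 CPM and Cdh2 at 51.9 and 40.7 CPM. It is called the main non-immune population here. Cluster 5 had 16 macrophage markers but only a dendritic marker among its leading genes, and was compared under its number. Clusters with no leading list, among them those called low in UMIs, or with genes of 2 types in the same cells stayed unnamed and entered shares and whole-tumour sums only. Few UMIs alone did not leave a cluster unnamed: cluster 10, led by macrophage genes and named, had a median of 807 UMIs, against 974 and 824.5 in the unnamed clusters 6 and 9.

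Cells are not independent replicates, so UMI counts were summed over the cells of a class in each library and the 6 sums were compared. Genes passing filterByExpr were tested with edgeR 4.0.16 (R 4.3.3), using TMM scaling, quasi-likelihood fits and a two-sided quasi-likelihood F test of exercise against sedentary. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. All log2 fold changes are exercise minus sedentary, levels are CPM (the UMIs of a gene scaled to a common total per sum) given as mean ± SD over the 3 libraries of a group, and SE is the standard error of a log2 fold change. There were 4 main comparisons: all kept cells (whole tumour), the main non-immune population, macrophage and monocyte-like cells, and CD8 T-like cells. Every other named class with at least 20 cells in each library was compared in the same way. Shares of cells were compared with the edgeR quasi-likelihood test on cell numbers, and by an exact two-sided permutation test. With 3 libraries against 3, that exact test cannot give a p below 0.10. All p-values measure the spread between these 6 libraries alone, and the labels do not state that each library is a separate mouse.

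A set of 28 gene lists was tested in the 4 main comparisons where at least 5 members were measured, using camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Camera asks whether members moved more in one direction than the other tested genes. It was repeated with the correlation estimated from the data, and fry tested whether members moved on balance in one direction. A list's score is the mean log2 CPM of its members, compared by the exact permutation test. Named genes followed a rule: in a main comparison, up to 10 genes past the threshold in each direction with groups that did not overlap, or, where none passed, the 3 with the smallest unadjusted p in each direction. In other classes up to 3 genes each way past the threshold were named. A fixed set of focus genes per comparison, and the 2 to 4 members of a list with the smallest unadjusted p, were added. Where another gene is named, that is said. Values of 3 of these genes are not reported here. Groups, tests, gene lists, marker lists, the rule for named genes and most alternatives were fixed before the data were examined. Whether the effect of exercise differed between 2 classes was tested with an edgeR model holding library as a block and an interaction term, for every pair of 6 classes.

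Alternatives were RLE size factors in place of TMM, the DESeq2 1.42.0 Wald test, no filter on low counts, doublets kept, a mitochondrial limit of 10%, Leiden resolution 2, counts thinned to the smallest library, shares of immune cells only, TMM over classes, and leaving out each library in turn. A further 5 kinds were added after the data had been seen: removal of doublets at the expected rate, cluster 5 counted with macrophage and monocyte-like cells, sedentary 2 and exercise 5 left out together, large neutrophil-like cells left out, and cluster 7 left out for the hypoxia list. No 2 libraries of a group were copies of each other, and the smallest chi-square per gene between a pair was 85.2. TMM and RLE placed the median log2 fold change of each comparison within 0.03 of 0.

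The tests were tried on simulated data in which 200 genes were changed in counts drawn to match these sums. In whole-tumour sums edgeR called 93 genes, 9 of them falsely, and DESeq2 called 186, 72 of them falsely. In the main non-immune population edgeR called 128 with 11 false calls, and DESeq2 194 with 57 false calls. The 2 tests were closer in macrophage and monocyte-like cells, where edgeR called 101 with 8 false calls and DESeq2 106 with 10. In CD8 T-like cells edgeR called 106 with 4 false calls and DESeq2 89 with 2. EdgeR found 41.3%, 62.7%, 51.6% and 61.0% of the genes changed by a factor of 2 in whole tumour, main non-immune population, macrophage and monocyte-like cells and CD8 T-like cells, and 7.58%, 26.5%, 4.41% and 10.8% of those changed by 1.5. Camera found 4 of 4 lists shifted by a factor of 1.3 in each of the 4 comparisons, with 1 false list in the main non-immune population and 0 in the others. Simulated genes varied independently of each other, which real list members do not. The fit with no filter on low counts was not tried on simulated data, so its rate of false calls is not known. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.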

Results

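Single-cell RNA was measured in whole dissociated YUMMER1.7 melanoma tumours from 6 libraries of 2 groups: sedentary 1, 2 and 3, and exercise 5, 6 and 8. The comparison implied by the design is treadmill running against no running, in the whole tumour and in each kind of cell it holds. The libraries held 125685480, 107247040 and 124510129 UMIs in the sedentary group and 97426009, 131778565 and 127801517 in the exercise group. After filtering, 7826, 7119 and 9371 sedentary cells and 7993, 9297 and 9800 exercise cells remained. Sedentary 2 and exercise 5 were the shallowest per cell, with medians of 6499 and 5902 UMIs against 10473 to 12426.5 in the other libraries. The same pair had the highest shares of immune cells, 44.4% and 50.2%, against 20.5% to 29.9% in the others. No batch is given in the labels.

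The cells fell into a main non-immune population, which made up 56.3 ± 12.3% of sedentary and 54.9 ± 13.9% of exercise cells, and immune and stromal classes. Immune cells made up 31.6 ± 12.1% of sedentary and 34.6 ± 13.6% of exercise cells (exact two-sided permutation p = 0.7). Macrophage and monocyte-like cells were the largest named immune class, at 13.6 ± 6.05% and 11.3 ± 3.78%. CD8 T-like cells, which carry the cytotoxic response against tumours, stood at 4.53 ± 2.29% and 6.21 ± 5.13%, with 12.1% in exercise 5 and 2.98% and 3.54% in exercise 6 and 8. NK-like cells were at 1.67 ± 0.435% and 2.33 ± 0.523%, Treg-like cells at 0.937 ± 0.652% and 0.923 ± 0.255%, and dendritic-like cells at 0.958 ± 0.345% and 1.58 ± 0.701%. Neutrophil-like cells were at 2.46 ± 1.12% in sedentary and 1.42 ± 1.54% in exercise libraries. Mast-like cells stood at 0.379 ± 0.0970% and 0.470 ± 0.156%, B-like cells at 0.0965 ± 0.0654% and 0.221 ± 0.264%, and Siglech-expressing dendritic-like cells at 0.321 ± 0.201% and 0.168 ± 0.0293%. The B-like share was 0.526% in exercise 5 and 0.0753% and 0.0612% in exercise 6 and 8. Its log2 fold change ranged from -0.45 to 1.64 without each library in turn. Fibroblast-like cells were at 0.0714 ± 0.0725% and 0.222 ± 0.230%, and endothelial-like cells at 0.119 ± 0.0212% and 0.124 ± 0.0444%. Cluster 5, led by Ly6i, H2-DMb1, Mgl2 and H2-Ab1 and not named, stood at 4.23 ± 2.55% and 6.77 ± 3.09%. Unnamed cells with few UMIs made up 10.5 ± 2.08% and 8.78 ± 0.438%. Of the 18 classes, 0 passed the edgeR test of shares (0 at an unadjusted p under 0.05, smallest adjusted p = 0.705), so no difference in composition passed. Without exercise 5, in which 3.19% of cells were neutrophil-like against 0.430% and 0.633% in exercise 6 and 8, the neutrophil-like share passed at a log2 fold change of -2.20, lower in both remaining exercise libraries than in all 3 sedentary ones.

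**Figure D1:**
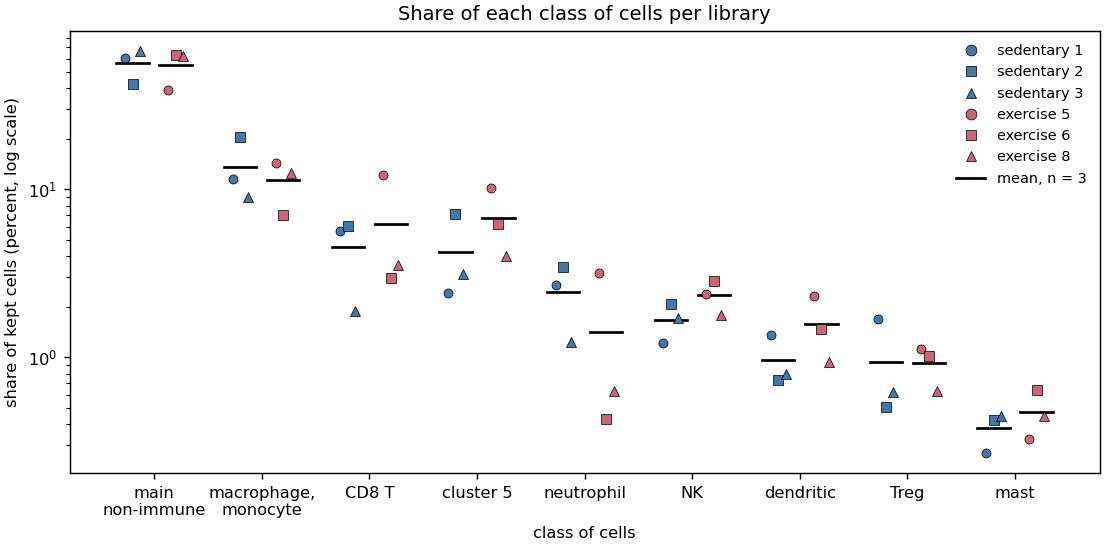
Share of kept cells (percent, log scale) for 9 classes of cells in each library, with sedentary and exercise libraries as separate symbols and a line at each group's mean of 3. The groups overlapped in each of these classes, and exercise 5 had the highest CD8 T-like share, 12.1%.

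In the whole tumour, 2 extracellular matrix genes and a Wnt ligand gene were among those named for the smallest unadjusted p. Tinagl1, which encodes a matricellular protein, stood at 16.1 ± 2.41 CPM in sedentary and 37.6 ± 3.29 CPM in exercise libraries (log2 fold change 1.22, SE 0.13). Dcn, the gene of the small collagen-binding proteoglycan decorin, stood at 376.1 ± 69.9 and 215.1 ± 8.59 CPM (-0.81, SE 0.13). Wnt5a, a Wnt ligand tied to invasive melanoma states, stood at 60.4 ± 8.92 and 35.1 ± 3.87 CPM (-0.78, SE 0.13). All 3 genes separated the groups, as did Anxa8 (0.0463 ± 0.00252 and 0.261 ± 0.0177 CPM), 2010111I01Rik (29.7 ± 0.641 and 40.5 ± 2.77 CPM) and Gm1673 (46.3 ± 2.52 and 28.8 ± 2.16 CPM). None of these genes passed edgeR. They were chosen for the smallest unadjusted p in each direction, a choice that favours groups that do not overlap. With 3 libraries against 3 a gene separates the groups by chance with a probability of 0.10, so separation alone is no support. Of 15477 genes tested, 0 passed, with 408 at an unadjusted p under 0.05, a smallest adjusted p of 0.48 and 18 calls by DESeq2, 4 higher and 14 lower in exercise. If no gene differed, a share of 0.05 of the tested genes would lie under that unadjusted p. In all 4 main comparisons the edgeR count lay below that share. On simulated whole-tumour counts DESeq2 called 72 unchanged genes among 186, so its calls are given as counts beside edgeR's.

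Genes marking immune infiltration differed little against their spread. Ptprc, the pan-leukocyte gene, stood at 89.8 ± 49.2 and 101.7 ± 54.7 CPM, Cd3e at 13.2 ± 7.39 and 14.3 ± 9.04 CPM, and Cd8a at 9.79 ± 4.91 and 12.1 ± 7.93 CPM. The lymphocyte subset genes Cd4 (0.37), Foxp3 (-0.27) and Ncr1 (0.36) and the macrophage gene Adgre1 (0.52) had log2 fold changes within 2 SE of 0. Ifng, the gene of interferon gamma, stood at 5.73 ± 4.18 and 5.69 ± 4.32 CPM, Gzmb had a log2 fold change of -0.09, and the interferon-induced genes Cxcl9 and Cxcl10 had 0.28 and -0.25. The neutrophil gene S100a8 stood at 100.6 ± 62.3 and 35.8 ± 34.3 CPM (-1.49, SE 0.81). Il6 stood at 0.330 ± 0.146 and 0.147 ± 0.0928 CPM (-1.18, SE 0.54). Mki67, Vegfa, Arg1, Pecam1 and Col1a1 had log2 fold changes of 0.11, -0.19, 0.65, 0.06 and 0.84. Without each library in turn Arg1 ranged from -0.14 to 1.55 and Col1a1 from -0.046 to 1.17, and Mki67 and Pecam1 also changed sign. The melanocyte regulator Sox10 had 4 UMIs in all and was not tested.

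Several gene lists passed camera with its preset correlation in the whole tumour, while 0 passed with an estimated correlation and 0 by fry, here and in the 3 comparisons below. The hypoxia list, targets of the oxygen-sensing HIF factors, fell as a group: 20 of 20 members had a lower mean in exercise, with a median log2 fold change of -0.41 (camera adjusted p = 4.91e-11, and adjusted p = 0.858 with an estimated correlation). Ankrd37 stood at 45.1 ± 11.6 and 27.6 ± 7.59 CPM, Mxi1 at 75.8 ± 13.7 and 52.9 ± 13.2 CPM and Ddit4 at 28.8 ± 3.68 and 20.7 ± 5.55 CPM. The list score was 6.31 ± 0.31 in sedentary and 5.85 ± 0.47 in exercise libraries (exact two-sided permutation p = 0.3). The glycolysis list (median -0.21, 13 of 18 lower, adjusted p = 0.00755), led by Pgk1 (482.6 ± 87.9 and 333.8 ± 53.7 CPM) and Gapdh (1716 ± 103 and 1406 ± 172 CPM), moved in the same direction. So did the immediate early list (-0.22, 17 of 20 lower, adjusted p = 0.00755), the NF-kB list (-0.18, 16 of 20 lower, adjusted p = 0.00166) and the mesenchymal list (-0.04, 13 of 20 lower, adjusted p = 0.036), whose leading members were Wnt5a, Tnc (9.87 ± 6.97 and 2.70 ± 0.470 CPM) and Mmp14 (243.4 ± 16.95 and 208.0 ± 5.42 CPM). With an estimated correlation the adjusted p was 0.858 for the immediate early and mesenchymal lists and 0.864 for the glycolysis and NF-kB lists.

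Antigen presentation lists rose in the whole tumour. The MHC-I list, the machinery that shows peptides to CD8 T cells, had a median of 0.18 with 18 of 20 members higher (adjusted p = 1.66e-05), including Erap1 (27.5 ± 4.08 and 34.5 ± 3.78 CPM) and Tap2 (22.6 ± 2.93 and 28.4 ± 6.46 CPM). The MHC-II list had a median of 0.59 with 11 of 11 members higher (adjusted p = 2.24e-05), including H2-Eb1 (162.3 ± 48.5 and 256.4 ± 115 CPM) and Ciita (9.13 ± 4.38 and 16.4 ± 8.89 CPM). Cluster 5, led by MHC-II genes among others, and dendritic-like cells also had higher mean shares in exercise (4.23% and 6.77%, and 0.958% and 1.58%), which did not pass. The alternative activation list (0.42, 15 of 20 higher, adjusted p = 0.00755, led by Lyve1 and Mgl2), the one-carbon list (0.11, 15 of 18, adjusted p = 0.00755, led by Phgdh), the G2/M list (0.11, 18 of 20, adjusted p = 0.0101, led by Cdc20) and the oxidative phosphorylation list (0.05, 20 of 23, adjusted p = 0.00832, led by Ndufa2) also passed. With an estimated correlation the adjusted p was 0.858 for all of these except G2/M, at 0.864. In all, 11 of 28 lists passed and 17 did not. Over all genes 0 of the 504 list members tested rose or fell, and adjusted over the list alone 1 did, Wnt5a in the mesenchymal list. Of the 11 lists, hypoxia was called without each library in turn, with a median of -0.20 without exercise 6. Without sedentary 1 the MHC-I (median 0.06), one-carbon (0.14) and oxidative phosphorylation (0.04) lists did not pass. Without sedentary 2 the glycolysis (-0.09), oxidative phosphorylation (0.05), mesenchymal (-0.06), immediate early (-0.06) and NF-kB (0.14) lists did not. Without sedentary 3 this held for the G2/M (0.05), glycolysis (-0.16), mesenchymal (-0.04) and alternative activation (0.24) lists. Without exercise 5 it held for the MHC-II (0.16), one-carbon (0.04), oxidative phosphorylation (0.05), mesenchymal (-0.05) and alternative activation (0.06) lists. Without exercise 6 it held for the G2/M (-0.01), glycolysis (-0.05), oxidative phosphorylation (0.05), mesenchymal (-0.04), immediate early (-0.15) and NF-kB (0.06) lists.

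**Figure D2:**
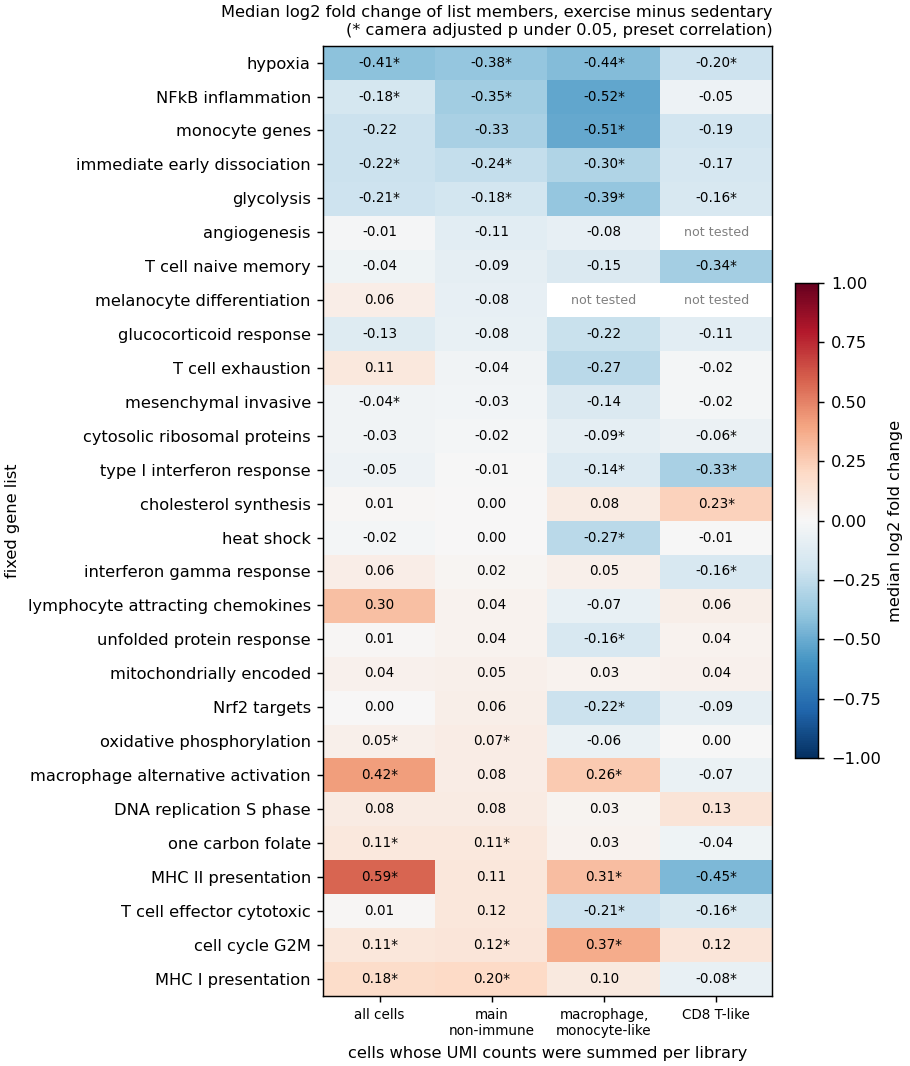
Median log2 fold change (exercise minus sedentary, colour scale and printed value) of the members of 28 fixed gene lists in 4 sets of cells, all cells, main non-immune, macrophage and monocyte-like and CD8 T-like, with a star where camera passed with its preset correlation. The hypoxia list lay at -0.41, -0.38, -0.44 and -0.20 in the 4 sets.

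In the main non-immune population, 2 secreted-factor genes had the smallest unadjusted p. Tinagl1 (chromosome 4, 130164454 to 130175122, mm10) stood at 17.4 ± 2.34 CPM in sedentary and 42.2 ± 2.94 CPM in exercise libraries (log2 fold change 1.28, SE 0.12, adjusted p = 0.081 by edgeR). Sfrp2, a secreted modulator of Wnt signalling (chromosome 3, 83766321 to 83774316), stood at 2.12 ± 0.480 and 0.188 ± 0.0858 CPM (-3.48, SE 0.35, adjusted p = 0.081). Both missed the threshold. With no filter on low counts, a setting not tried on simulated data, both passed edgeR with an adjusted p of 0.00276. Both also passed DESeq2, which on simulated counts of this population called 57 unchanged genes among 194. Wnt5a (chromosome 14, 28504750 to 28527448) stood at 65.7 ± 9.68 and 38.9 ± 1.49 CPM (-0.76, SE 0.11), and Gm1673 (chromosome 5, 33983433 to 33985013) at 49.8 ± 1.48 and 31.4 ± 1.49 CPM (-0.67, SE 0.08). Anxa8 (chromosome 14, 34085981 to 34100571) and Slc35f2 (chromosome 9, 53771538 to 53818154) were near the detection limit, at 0.0517 ± 0.00502 and 0.286 ± 0.00664 CPM and at 0.127 ± 0.0189 and 0.464 ± 0.0716 CPM. The sums behind these values held between 74457228 and 115469017 UMIs per library. Of 14492 genes, 0 passed edgeR, with 560 at an unadjusted p under 0.05 and 32 calls by DESeq2 (9 higher, 23 lower). None of the focus genes of tumour recognition and metabolism passed: H2-K1 was at 1345 ± 303 and 1536 ± 70.5 CPM, B2m had a log2 fold change of 0.10, Cd274 of -0.23, Irf1 of -0.08, Mki67 of 0.08, Vegfa of -0.13, Ldha of -0.18, Nqo1 of 0.14 (with groups that did not overlap), Axl of -0.03 and Myc of -0.02. Slc2a1, the glucose transporter gene, stood at 102.6 ± 30.2 and 73.8 ± 40.4 CPM, and Hmox1, an oxidative stress gene, at 58.8 ± 29.6 and 28.8 ± 13.9 CPM (-1.03, SE 0.46). Of the pigment cell genes, Mitf was at 9.80 ± 0.985 and 9.86 ± 2.06 CPM and Pmel had a log2 fold change of -0.08. Sox10 (2 and 0 UMIs in the sedentary and exercise groups), Mlana (2 and 5), Tyr (4 and 1), Dct (4 and 5) and Ngfr (1 and 4) had too few UMIs to test.

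The mix of clusters in this population differed between libraries. Clusters 0 and 3 held the largest parts of the pooled sedentary cells (20.7% and 20.6%), and clusters 0 and 1 those of the exercise cells (23.01% and 22.1%), with cluster 3 at 10.5% in exercise. These are pooled values: by library cluster 3 held 31.9%, 8.496% and 17.8% against 5.70%, 13.1% and 10.45%, so the groups overlapped, and cluster 1 held 15.55%, 7.97% and 20.2% against 17.6%, 21.4% and 25.1%. Cluster 7, led by Cxcl1, Ero1l and Slc2a1, held 12.8% of sedentary and 5.51% of exercise cells of the population, and 8.45%, 19.3% and 12.9% against 13.6%, 0.884% and 5.86% by library. Cluster 11, led by Ibsp, Dmp1, Spp1 and Tinagl1, held 3.87% and 8.24%, and 2.01%, 2.22% and 6.09% against 0.870%, 7.34% and 12.8% by library, so that exercise 5 was the lowest of the 6.

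The hypoxia list also fell in the main non-immune population, with 20 of 20 members lower and a median of -0.38 (camera adjusted p = 1.2e-08, and adjusted p = 0.717 with an estimated correlation). Ankrd37 stood at 45.5 ± 11.2 and 28.9 ± 8.64 CPM, Mxi1 at 74.8 ± 12.2 and 53.1 ± 13.2 CPM and P4ha1, a collagen prolyl hydroxylase gene, at 207.6 ± 43.4 and 163.0 ± 19.2 CPM. The scores were 5.98, 6.49 and 6.51 in sedentary 1, 2 and 3 and 6.31, 5.31 and 6.05 in exercise 5, 6 and 8, so the groups overlapped (exact two-sided permutation p = 0.3). Those of sedentary 1, exercise 6 and exercise 8 all lay below those of sedentary 2, sedentary 3 and exercise 5, a split that cuts across the groups. Beside it, the glycolysis list (-0.18, 14 of 18 lower, adjusted p = 0.00439, led by Pgk1 at 477.2 ± 83.8 and 326.0 ± 51.7 CPM), the immediate early list (-0.24, 17 of 20, adjusted p = 0.00507, led by Ppp1r15a) and the NF-kB list (-0.35, 13 of 18, adjusted p = 0.00129, led by Saa3, Il6 and Nfkbia) fell. The neutrophil gene S100a8 stood at 24.4 ± 22.5 and 8.79 ± 4.33 CPM in this population. With an estimated correlation the adjusted p of the glycolysis, immediate early and NF-kB lists was 0.831, 0.717 and 0.717. The MHC-I list rose (0.20, 18 of 20 higher, adjusted p = 2.14e-05), with a score of 7.04 ± 0.28 and 7.23 ± 0.12 (exact two-sided permutation p = 0.4). The oxidative phosphorylation (0.07, 21 of 23, adjusted p = 0.00439), one-carbon (0.11, 17 of 18, adjusted p = 0.0114) and G2/M lists (0.12, 18 of 20, adjusted p = 0.0114) rose by less, and with an estimated correlation the adjusted p of the last was 0.939 and of the other 3 rising lists 0.717.

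Of 28 lists in the main non-immune population 8 passed. The mesenchymal list did not (median -0.03, adjusted p = 0.0635), but adjusted over the list alone 2 of its 20 members fell, Wnt5a and Tnc (10.01 ± 7.495 and 1.80 ± 0.8002 CPM), while over all genes 0 did. The interferon gamma (0.02), type I interferon (-0.01), MHC-II (0.11), T cell exhaustion (-0.04), T cell naive and memory (-0.09), S phase (0.08), mitochondrially encoded (0.05), angiogenesis (-0.11), unfolded protein response (0.04), Nrf2 target (0.06), melanocyte (-0.08) and glucocorticoid (-0.08) lists did not pass. The medians and tests of the heat shock, cholesterol synthesis and alternative activation lists differed in sign, with medians of 0.00, 0.00 and 0.08 and a direction of down. Hypoxia was called without each library in turn, with medians of -0.55 without sedentary 1, -0.56 without exercise 5, -0.27 without sedentary 3 and -0.18 without exercise 6. Without sedentary 1 the MHC-I (0.07) and one-carbon (0.13) lists did not pass, and without sedentary 2 the glycolysis (-0.08), immediate early (-0.15) and NF-kB (0.01) lists did not. Without sedentary 3 the one-carbon (0.11), G2/M (0.05), glycolysis (-0.15) and immediate early (-0.21) lists did not pass. Without exercise 5 this held for the one-carbon (0.02), G2/M (0.09), oxidative phosphorylation (0.04) and immediate early (-0.18) lists, and without exercise 6 for the G2/M (0.01), glycolysis (-0.05), oxidative phosphorylation (0.06) and NF-kB (-0.22) lists.

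**Figure D3:**
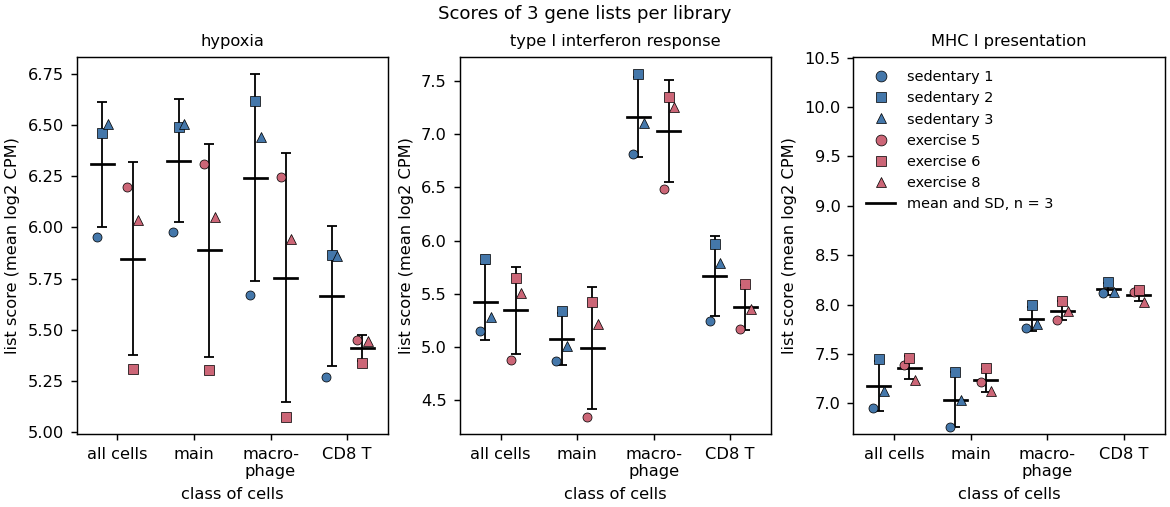
Scores of the hypoxia, type I interferon and MHC-I lists (mean log2 CPM of the members) in all cells, the main non-immune population, macrophage and monocyte-like cells and CD8 T-like cells, with each library as a symbol and the mean and SD of 3 libraries per group as lines. In the main population exercise 6 had the lowest hypoxia score, 5.31, and exercise 5 the lowest type I interferon score, 4.34.

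In macrophage and monocyte-like cells, Ccl4, a chemokine that draws T cells and monocytes, showed the smallest p. It stood at 195.3 ± 23.7 CPM in sedentary and 84.7 ± 11.1 CPM in exercise libraries (chromosome 11, 83662584 to 83664683, log2 fold change -1.20, SE 0.15, adjusted p = 0.238 by edgeR). It passed DESeq2 (adjusted p = 5.61e-06), and edgeR when cluster 5 was counted with this class (log2 fold change -1.23, adjusted p = 0.0446). In cluster 5 by itself the log2 fold change of Ccl4 was only -0.16. The mean share of cluster 5 was 4.23% in sedentary and 6.77% in exercise libraries, so the pooled call does not show a fall in the added cells. Mmp13, a collagenase gene (chromosome 9, 7272514 to 7283331), stood at 373.0 ± 79.3 and 174.4 ± 40.3 CPM, and Pgf, a growth factor of the VEGF family (chromosome 12, 85166635 to 85177790), at 25.8 ± 7.49 and 8.48 ± 3.49 CPM. Alox5, the 5-lipoxygenase gene (chromosome 6, 116410077 to 116461178), stood at 1.25 ± 0.797 and 5.84 ± 1.93 CPM, Arhgap19 (chromosome 19, 41766588 to 41802047) at 19.9 ± 1.71 and 34.6 ± 3.09 CPM, and Zfp607a (chromosome 7, 27857527 to 27880825) at 2.26 ± 0.428 and 5.90 ± 0.399 CPM. All 6, chosen for the smallest unadjusted p in each direction, separated the groups, and none passed edgeR with the filter. With no filter on low counts, a setting not tried on simulated data, Ccl4, Mmp13, Pgf and Alox5 passed. Mmp13 and Pgf also passed DESeq2, which on simulated counts of this class called 10 unchanged genes among 106. Of 10408 genes, 0 passed edgeR, with 232 at an unadjusted p under 0.05, a smallest adjusted p of 0.238 and 4 calls by DESeq2 (1 higher, 3 lower), from 6221 cells and 2108657 to 5862775 UMIs per library. Among focus genes, Cxcl9 stood at 1132 ± 210 and 1414 ± 47.2 CPM, H2-Aa at 2360 ± 444 and 3014 ± 139 CPM, Il1b at 686.8 ± 381 and 377.3 ± 108 CPM and Arg1 at 129.5 ± 46.6 and 179.2 ± 60.1 CPM. Cd74 (0.23), Mrc1 (0.26), Trem2 (-0.18), Spp1 (0.28), C1qa (0.13), Apoe (0.15), Ccr2 (0.27), Cxcl10 (-0.14), Nos2 (-0.23), Tnf (-0.31), Ccl2 (-0.21), Ly6c2 (-0.34), Cd274 (-0.34), Vegfa (-0.35) and Hmox1 (-0.62) had log2 fold changes smaller than 2 SE. Il10 had 19 and 27 UMIs and was not tested. Over pooled cells cluster 10 led this class in both groups (35.6% and 37.1%), but cluster 12 led in sedentary 2 (40.6% against 22.6%) and exercise 5 (32.4% against 22.2%). Cluster 16 held 12.6% of sedentary and 21.6% of exercise cells, and 21.1%, 5.01% and 16.6% against 18.6%, 23.4% and 23.3% by library, so the groups overlapped and sedentary 2 was the lowest. Cluster 13, led by Mmp12, Arg1, Hspa1a and Mmp13, held 23.8% and 16.8%, and 8.204%, 31.8% and 26.7% against 26.8%, 5.50% and 13.5% by library.

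Lists of cell division and antigen presentation rose in macrophage and monocyte-like cells. The G2/M list had 20 of 20 members higher and a median of 0.37 (camera adjusted p = 1.53e-09), with Kif11 at 26.8 ± 6.86 and 40.9 ± 9.89 CPM and Cdc20 at 17.5 ± 4.40 and 26.6 ± 4.89 CPM. The MHC-II list had 11 of 11 higher and a median of 0.31 (adjusted p = 4.88e-06), with Ciita, the master regulator of these genes, at 82.1 ± 11.01 and 115.8 ± 32.2 CPM and H2-DMa at 385.7 ± 37.0 and 478.1 ± 49.1 CPM. Its score was 8.08 ± 0.24 and 8.42 ± 0.09 (exact two-sided permutation p = 0.1, the smallest this design allows). The alternative activation list rose (0.26, 12 of 17, adjusted p = 0.0172), with Clec10a at 23.7 ± 10.9 and 43.7 ± 8.83 CPM and Cd163 at 4.74 ± 2.68 and 10.2 ± 5.31 CPM. With an estimated correlation the adjusted p of each of these 3 lists was 0.497.

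A larger set of lists fell in these cells, all with an adjusted p of 0.497 to 0.663 with an estimated correlation. The hypoxia list (-0.44, 19 of 20 lower, adjusted p = 3.94e-06, Ankrd37 at 58.6 ± 30.04 and 25.9 ± 9.77 CPM) and the glycolysis list (-0.39, 16 of 18, adjusted p = 6.82e-05, Gapdh at 2373 ± 528 and 1680 ± 337 CPM) were lower. The NF-kB list (-0.52, 17 of 18 lower, adjusted p = 3.94e-06) was led by Ccl4, Ccl3 (60.5 ± 11.01 and 32.8 ± 15.95 CPM) and the neutrophil attractant Cxcl2 (86.8 ± 57.8 and 33.9 ± 11.1 CPM). The monocyte list (-0.51, 12 of 14, adjusted p = 0.00285) was led by Hp (88.5 ± 51.6 and 45.7 ± 19.5 CPM) and F10. Stress lists were lower too: immediate early (-0.30, 18 of 19, adjusted p = 0.000128, Ier3 at 344.3 ± 113 and 194.2 ± 73.3 CPM), heat shock (-0.27, 13 of 14, adjusted p = 0.000532, Hspa1a at 154.6 ± 136 and 53.5 ± 36.0 CPM), Nrf2 target (-0.22, 16 of 21, adjusted p = 0.00198, Gsr at 164.0 ± 91.7 and 89.9 ± 34.5 CPM) and unfolded protein response (-0.16, 15 of 16, adjusted p = 0.0128). The effector list (-0.21, 11 of 14, adjusted p = 0.00756) was led by Ccl4, Ccl3 and Srgn rather than by granzymes. The type I interferon (-0.14, 18 of 24, adjusted p = 0.0172) and ribosomal protein (-0.09, 23 of 24, adjusted p = 0.0011) lists fell as well. The neutrophil gene S100a8 was at 32.5 ± 24.6 and 12.2 ± 11.2 CPM in this class.

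In all, 14 of 27 lists passed in macrophage and monocyte-like cells. Over all genes 0 of 445 members passed, and adjusted over the list alone Ccl4 fell in the NF-kB, effector and chemokine lists and Pgf in the angiogenesis list. The MHC-I (median 0.10, adjusted p = 0.0598), chemokine (-0.07, adjusted p = 0.074) and interferon gamma (0.05, adjusted p = 0.178) lists did not pass. The G2/M and MHC-II lists were called without each library in turn, the former with medians of 0.16 without sedentary 2 and 0.20 without exercise 6. Without sedentary 2, which had the highest monocyte score (8.87 against 7.47 and 7.78 in sedentary 1 and 3), 8 lists lost their call: type I interferon (0.09), effector (0.06), Nrf2 target (-0.06), glycolysis (-0.16), immediate early (-0.06), NF-kB (-0.02), alternative activation (0.24) and monocyte (0.10). Without exercise 8 the effector (-0.17), immediate early (-0.17), alternative activation (0.05) and monocyte (-0.32) lists did not pass, and without exercise 6 the hypoxia (-0.21), Nrf2 target (-0.13) and unfolded protein response (-0.07) lists did not. Without sedentary 3 the heat shock (0.02), unfolded protein response (-0.02) and ribosomal (-0.02) lists did not pass, and without exercise 5 the unfolded protein response (-0.09) did not and the type I interferon median was 0.04. With cluster 5 added to the class the G2/M (0.05), Nrf2 target (-0.12), alternative activation (0.15) and ribosomal (-0.03) lists did not pass, and the exhaustion (-0.19), chemokine (-0.34), glucocorticoid (-0.28) and cholesterol synthesis (0.23) lists did.

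In CD8 T-like cells, Serpinb9b, a granzyme B inhibitor family gene (chromosome 13, 33027416 to 33041884), fell from 30.1 ± 13.8 CPM in sedentary to 6.00 ± 0.821 CPM in exercise libraries. The log2 fold change was -2.33 (SE 0.35, edgeR adjusted p = 0.0442), with 3 of 3 exercise libraries below all 3 sedentary ones. It was the only gene of 8832 to pass, with 242 at an unadjusted p under 0.05 and 1 call by DESeq2. The counts were 44, 77 and 14 UMIs in sedentary 1, 2 and 3 and 19, 5 and 10 in exercise 5, 6 and 8, from class totals of 600401 to 3145733 UMIs. Reads shared with other genes of its family were not measured. It led sub-cluster 11 of the T and NK-like cells together with Gzme, Gzmf and Gzmd, and this sub-cluster held 7.91% of sedentary and 2.26% of exercise CD8 T-like cells (7.68%, 8.86% and 6.22% against 0.516%, 5.42% and 4.61% by library). Serpinb9b kept its direction without each library but passed only without sedentary 1 (-2.63, adjusted p = 0.00481). The values were -1.82 without sedentary 2 (adjusted p = 0.121), -2.41 without sedentary 3 (0.1), -2.31 without exercise 5 (0.361), -2.27 without exercise 6 (0.132) and -2.40 without exercise 8 (0.237), and with doublets kept the adjusted p was 0.102. With no filter on low counts, a setting not tried on simulated data, the edgeR adjusted p of Serpinb9b was 6.92e-11. With thinned counts or without both sedentary 2 and exercise 5 no gene passed. Over the alternatives with a value for it the adjusted p of Serpinb9b ranged from 6.92e-11 to 0.361.

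None of the effector focus genes of CD8 T-like cells passed. Gzma, the granzyme A gene, stood at 251.5 ± 127 and 70.9 ± 68.6 CPM (log2 fold change -1.93, SE 0.46) and did not pass over all genes. It passed without exercise 6 (-2.97, edgeR adjusted p = 0.00328) and with no filter on low counts, and over its alternatives the adjusted p ranged from 1.12e-26 to 1. The fit with no filter was not tried on simulated data, so its pass carries little weight beside the spread between libraries. Gzmb stood at 841.0 ± 306 and 623.1 ± 86.9 CPM (-0.44, SE 0.19), Ifng at 327.5 ± 176 and 266.5 ± 111 CPM (-0.34, SE 0.31), Prf1 had a log2 fold change of -0.16, Tnf of -0.49, Gzmk of 0.47 and Ccl5 of -0.02. Without each library in turn Gzmk ranged from -0.86 to 0.89, and Ifng, Prf1 and Ccl5 also changed sign. Checkpoint genes were close between groups: Pdcd1 was at 232.4 ± 31.4 and 227.9 ± 25.7 CPM, and Havcr2, Lag3, Tigit and Tox had log2 fold changes of -0.11, -0.18, 0.25 and 0.23. Tcf7, a gene of stem-like T cells, had 0.12, Il7r -0.55, Cxcr6 -0.04, Cxcr3 0.43 and Mki67 0.25. The oxidative stress regulator Nfe2l2 stood at 47.9 ± 9.23 and 36.6 ± 2.35 CPM (-0.32), Hmox1 had -0.53, and the folate enzyme gene Mthfd2 was at 75.5 ± 5.60 and 76.1 ± 12.8 CPM (0.02). Nqo1 had 4 and 7 UMIs and was not tested.

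The effector list fell in CD8 T-like cells (median -0.16, 16 of 22 members lower, camera adjusted p = 1.32e-05, and adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone Gzma and Gzme (100.5 ± 49.95 and 36.2 ± 30.9 CPM) fell and the chemokine gene Xcl1 rose (86.8 ± 26.8 and 186.8 ± 105 CPM), while over all genes 0 of the 22 passed. The MHC-II list had 7 of 7 members lower (-0.45, adjusted p = 1.99e-05, and adjusted p = 0.328 with an estimated correlation), and Cd74 (164.0 ± 84.1 and 80.6 ± 12.9 CPM) and Ctss (123.0 ± 11.1 and 90.9 ± 3.48 CPM) fell when adjusted over the list alone. These are also abundant transcripts of macrophages, and S100a8, which T cells lack, stood at 15.7 ± 14.4 and 2.53 ± 1.44 CPM in the same cells. The type I interferon list (-0.33, 22 of 23 lower, adjusted p = 2.77e-06) was led by Ifit3 (104.1 ± 45.0 and 60.5 ± 14.8 CPM) and Isg15 (136.7 ± 49.1 and 95.4 ± 8.81 CPM). Sub-cluster 8 of these cells, led by Ifit3, Rsad2 and Ifit1, held 8.87% of sedentary and 4.96% of exercise cells (6.77%, 11.7% and 7.35% against 4.95%, 5.42% and 4.61% by library). The interferon gamma list (-0.16, 18 of 23, adjusted p = 0.0141), the glycolysis list (-0.16, 15 of 16, adjusted p = 0.00142), the ribosomal protein list (-0.06, 21 of 24, adjusted p = 0.00702) and the MHC-I list (-0.08, 13 of 20, adjusted p = 0.0492) fell too, and with an estimated correlation the adjusted p of these 4 lists and the type I interferon list was 0.725. The hypoxia list (-0.20, 15 of 17, adjusted p = 0.00803, Bnip3 at 40.7 ± 14.0 and 22.9 ± 1.35 CPM) had an adjusted p of 0.765 with an estimated correlation. The naive and memory list (-0.34, 12 of 14, adjusted p = 0.00452) was led by S1pr1, the receptor for exit from tissue (9.75 ± 0.714 and 3.14 ± 2.81 CPM), with an adjusted p of 0.328 with an estimated correlation and a score of 4.90 ± 0.10 and 4.53 ± 0.02 (exact two-sided permutation p = 0.1).

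Cholesterol synthesis was the 1 list that rose in CD8 T-like cells (0.23, 15 of 17 members higher, adjusted p = 0.000242, and adjusted p = 0.564 with an estimated correlation), with Lss at 6.68 ± 0.531 and 9.87 ± 0.774 CPM. In all, 10 of 26 lists passed. The S phase (0.13, adjusted p = 0.0548), G2/M (0.12), Nrf2 target (-0.09), one-carbon (-0.04), unfolded protein response (0.04), NF-kB (-0.05) and chemokine (0.06) lists did not, although adjusted over the list alone Xcl1 rose in the last. For the exhaustion, oxidative phosphorylation, mesenchymal and heat shock lists the median was -0.02, 0.00, -0.02 and -0.01 and the test's direction was up, and none passed. The MHC-II and effector lists were called without each library in turn, the former with a median of -0.72 without sedentary 2 and the latter with -0.06 without sedentary 2, -0.25 without sedentary 3, -0.31 without exercise 5, -0.24 without exercise 6 and -0.10 without exercise 8. Without sedentary 2, 7 lists lost their call: interferon gamma (0.02), type I interferon (-0.09), MHC-I (-0.02), naive and memory (-0.04), hypoxia (-0.06), glycolysis (-0.07) and cholesterol synthesis (0.06). Without exercise 8 the interferon gamma (-0.13), MHC-I (-0.03) and naive and memory (-0.20) lists did not pass, and without sedentary 3 the MHC-I (-0.08), hypoxia (-0.07) and ribosomal (-0.03) lists did not. Without exercise 5 the glycolysis (-0.10) and ribosomal (-0.03) lists did not pass, nor did the ribosomal list without sedentary 1 (-0.03).

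In NK-like cells, Ccl4 rose from 59.5 ± 7.63 CPM in sedentary to 212.8 ± 65.3 CPM in exercise libraries (log2 fold change 1.82, SE 0.23, edgeR adjusted p = 0.00048), higher in 3 of 3 exercise libraries than in every sedentary one. Its counts were 22, 26 and 20 UMIs in sedentary and 122, 103 and 76 in exercise libraries, from 95 to 263 cells each. It was the 1 gene of 5221 to pass, with 163 at an unadjusted p under 0.05 and 1 call by DESeq2, and it passed without each library in turn (1.55 to 1.99, largest adjusted p = 0.00623). S100a8 stood at 15.7 ± 11.7 and 3.05 ± 2.64 CPM in NK-like cells. In Treg-like cells, the neighbouring chemokine gene Ccl3 (chromosome 11, 83647844 to 83649355) fell from 177.6 ± 26.9 to 23.5 ± 5.67 CPM (-2.87, SE 0.41, edgeR adjusted p = 0.000289), lower in 3 of 3 exercise libraries. Its counts were 64, 16 and 17 against 3, 4 and 2 UMIs, from 472 cells in all and 36 in the smallest library. It was the 1 gene of 2532 to pass, with 176 at an unadjusted p under 0.05 and 1 call by DESeq2, and it passed without each library in turn (-3.07 to -2.68, largest adjusted p = 0.038). S100a8 stood at 16.3 ± 22.6 and 4.75 ± 4.50 CPM in Treg-like cells.

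In neutrophil-like cells, Dcn (chromosome 10, 97479609 to 97518143) fell from 509.5 ± 62.5 to 67.6 ± 37.6 CPM (-2.73, SE 0.36, edgeR adjusted p = 0.00207), lower in 3 of 3 exercise libraries. The counts were 212, 169 and 120 against 24, 1 and 11 UMIs, from 40 to 255 cells per library. Decorin is a product of fibroblasts, and 84.9% of its UMIs lay in 37 of the 929 cells. These large cells had over 5 times the median UMIs of the class in their library and held 43.0% of all UMIs of the class. Col3a1, another fibroblast gene, stood at 1024 ± 442 and 490.9 ± 322 CPM in the class. Without the large cells the Dcn change was -1.82 (SE 0.51) and did not pass (adjusted p = 0.11), and without exercise 5 it was -2.71 and did not pass (0.154). With thinned counts 4 other genes passed (Wfdc17, Txnip, Gbp2 and Ctsl, seen after the fact) and Dcn did not. Over the alternatives with a value for Dcn the adjusted p ranged from 5.02e-07, with no filter on low counts, to 0.154. It was the 1 gene of 3993 to pass, with 191 at an unadjusted p under 0.05 and 2 calls by DESeq2. In cluster 5 (9624 genes), dendritic-like (5704) and mast-like cells (816), 0 genes passed edgeR, with 372, 316 and 43 at an unadjusted p under 0.05 and 0 calls by DESeq2 in each.

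**Figure D4:**
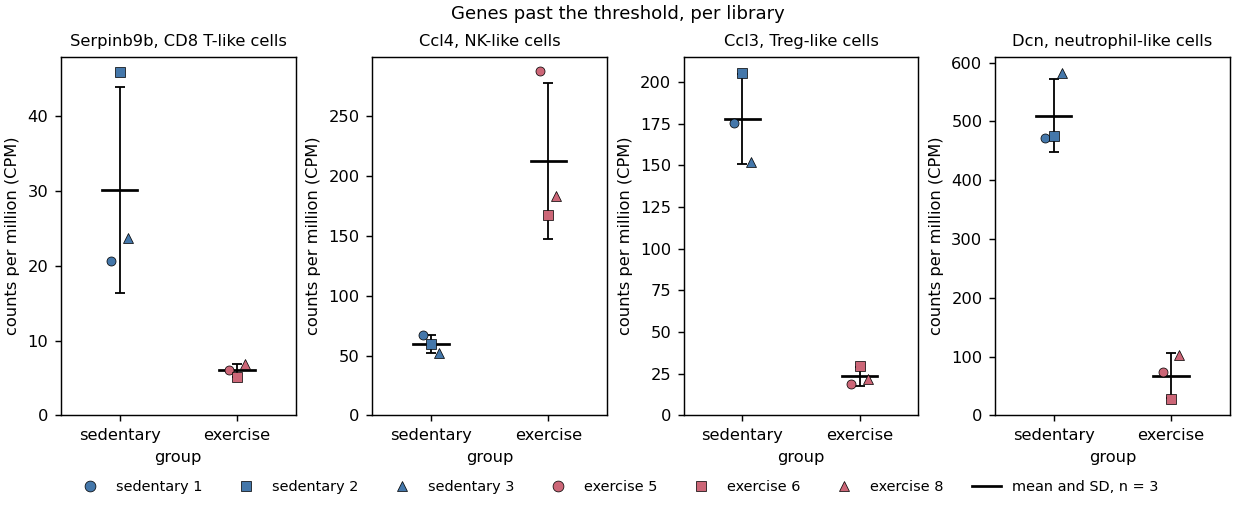
CPM of the 4 genes past the threshold, each in its class of cells (Serpinb9b in CD8 T-like, Ccl4 in NK-like, Ccl3 in Treg-like and Dcn in neutrophil-like cells), with each library as a symbol and the mean and SD of 3 libraries per group. The groups did not overlap in any of the 4, and Ccl4 alone was higher in exercise, at 212.8 against 59.5 CPM.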

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

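Leaving out each library was planned, but weighing the hypoxia list and Dcn by it was decided only after the results were seen, as were the tests of the hypoxia list without cluster 7, of Dcn in large cells and of doublets removed at the expected rate. The effect of exercise differed between classes of cells for 7 genes, by an interaction test with library as a block and p adjusted over the genes of each pair of classes.

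The inflammatory chemokines Ccl4 and Ccl3 gave 6 of the 12 differences. The exercise effect on Ccl4 was higher in NK-like than in macrophage and monocyte-like cells by a log2 of 3.004 (effects of 1.82 and -1.20, edgeR adjusted p = 4.22e-07) and higher than in cluster 5 by 1.98 (-0.16 there, adjusted p = 0.000728). It was lower in Treg-like than in NK-like cells by -3.33 (effect of -1.44 in Treg-like cells, adjusted p = 2.1e-07) and than in CD8 T-like cells by -2.10 (0.54 there, adjusted p = 0.000106). For Ccl3 the effect in Treg-like cells was lower than in NK-like cells by -5.14 (effects of -2.87 and 2.23, edgeR adjusted p = 0.000112) and than in CD8 T-like cells by -2.93 (0.06 there, adjusted p = 0.000504). Ifitm1, an interferon-induced membrane gene, had a higher effect in NK-like cells (0.33) than in macrophage and monocyte-like cells by 1.44 (edgeR adjusted p = 0.00175) and than in cluster 5 by 1.62 (adjusted p = 0.000309). Against cluster 5, Treg-like cells had a higher effect on the T cell receptor gene Trbc1 by 1.84 (edgeR adjusted p = 0.0114) and a lower one on the actin-binding gene Tmsb10 by -0.68 (adjusted p = 0.0173). In cluster 5, 0 T cell markers were raised. The effect on Gzma was higher in the main population than in CD8 T-like cells by 2.58 (effects of 0.68 and -1.93, edgeR adjusted p = 0.00867), and the main population should lack this gene. Spp1 differed between Treg-like and NK-like cells by 1.04 (effects of 1.11 and -0.16, edgeR adjusted p = 0.0244).

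Ccl4 in NK-like cells and Ccl3 in Treg-like cells are also products of macrophages, so RNA of those cells was weighed as a source. In NK-like cells 20 abundant macrophage genes, led by Cd74, Apoe and Lyz2, had a median log2 fold change of -0.0087 (upper quartile 0.21), where this source needed at least 0.91. In Treg-like cells only 9 genes met the rule, and their median was 0.19 (lower quartile 0.09), where it needed -1.43 or lower. The rule kept only genes at least 10 times lower in these cells than in macrophage and monocyte-like cells. Ccl4 stood at 133.9 CPM in NK-like and 142.3 CPM in macrophage and monocyte-like cells. Ccl3 stood at 93.4 CPM in Treg-like and 47.3 CPM in macrophage and monocyte-like cells. So RNA of abundant macrophage genes did not move this way, but the sets cannot stand in for Ccl4 or Ccl3 and do not settle this source. The 5 cells of each library with the most UMIs of the gene held 69.9% of the Ccl4 UMIs in NK-like and 83.0% of the Ccl3 UMIs in Treg-like cells. Ccl3 was seen in only 3, 3 and 1 Treg-like cells of exercise 5, 6 and 8, so its share was bound to be high there. Ccl4 was seen in 7.43% of sedentary and 10.5% of exercise NK-like cells, and Ccl3 in 10.6% and 2.85% of Treg-like cells, over pooled libraries. A change with exercise in a small part of these cells may explain the differences, as a hypothesis found and tested on the same 6 libraries. Sources other than macrophages were not tested. Sub-cluster 7 of the CD8 T-like cells was led by Ccl3 and Ccl4. Treg-like cells with Ccl3 had a higher median of UMIs than the class in each library. The medians ran from 2315 against 2249 in sedentary 2 to 8118 against 1046 in exercise 8. Cells with over 5 times the median held 4.72% of the Ccl3 UMIs and 11.3% of all UMIs of the Treg-like class.

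The hypoxia list fell in the main non-immune population with a median of -0.38. Without exercise 6, the library with the lowest score, the median was -0.18, and it stayed below 0 without each other library, but scores separated the groups only without sedentary 1. Without cluster 7, led by Cxcl1, Ero1l and Slc2a1, the median was -0.22 (quartiles -0.33 and -0.14), 19 of 20 members stayed below 0 and the list still passed (adjusted p = 6.3e-05, range over the alternatives 1.95e-14 to 0.717). That median lies within the members' spread of -0.19, above which the test would have pointed to the cluster, so a smaller share of cluster 7 as a main source, and a strong effect of exercise 6, cannot be told apart from a lower level of the members throughout the population. An effect of exercise stays open and was not tested apart from these.

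Dcn fell in neutrophil-like cells, which do not make decorin. From 7 genes that met the rule, free RNA of the main population would have given a log2 fold change of -0.82. The measured -2.73 lay -3.89 combined errors away. These 7, led by Hist1h2ap, Top2a and Ube2c, are mostly genes of dividing cells, and the rule kept only genes much lower in neutrophil-like cells. Dcn stood at 320.8 CPM there and 318 CPM in the main population, so the set cannot stand in for Dcn and does not settle this source. A single library is argued against, since the change lay between -2.97 and -2.61 without each library in turn, although without exercise 5 it did not pass (-2.71, adjusted p = 0.154). Large cells held 84.9% of the Dcn UMIs against 43.0% of all UMIs of the class. Neutrophil-like cells joined with other cells are therefore a candidate explanation, but the kind of cell is open. Fibroblast-like cells had Dcn at 5075 CPM and the main population at 318 CPM. The mean fibroblast-like share was lower in sedentary (0.0714%) than in exercise libraries (0.222%), which would run against the fall. That difference rests on exercise 5 (0.488%), with 0.0968% and 0.0816% in exercise 6 and 8. Sedentary 2 was at 0.1545%, so the groups overlapped. With doublets removed at the expected rate the change was -1.82 (SE 0.42, edgeR adjusted p = 0.154), and a decrease in the remaining cells stays open.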

How the results depend on the processing

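Alternatives chosen after seeing the data were doublets removed at the expected rate, cluster 5 added to macrophage and monocyte-like cells, sedentary 2 and exercise 5 both left out, large neutrophil-like cells left out, and cluster 7 left out. No paired analysis was possible because the groups share no replicate numbers. Except where said, the cause of a difference was not tested.

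RLE size factors left 204 of 205 values on the same side of the threshold. A 10% mitochondrial limit left the number of called genes unchanged in every comparison, and Leiden resolution 2 in all but neutrophil-like cells. Of the shares of classes 0 passed, and 0 passed under these 2 settings, among immune cells only or with TMM over classes, which says little because none was near the threshold. Ccl4 in NK-like and Ccl3 in Treg-like cells passed in every alternative run for them. DESeq2 called 18 genes in the whole tumour, 32 in the main population, including Tinagl1 and Sfrp2, 4 in macrophage and monocyte-like and 2 in neutrophil-like cells. With no filter on low counts edgeR called 2 genes in the main population, 14 in macrophage and monocyte-like, 35 in CD8 T-like, 40 in cluster 5, 44 in dendritic-like, 11 in mast-like, 10 in neutrophil-like, 10 in NK-like and 4 in Treg-like cells. The rate of false calls in that setting was not measured. Apart from it, edgeR counts changed in fewer comparisons. With doublets kept it called 0 in CD8 T-like and 2 in Treg-like cells. Counts thinned to the smallest library gave 0 in CD8 T-like and 4 in neutrophil-like cells, so at that depth no gene passed in CD8 T-like cells. Leiden resolution 2 gave 2 in neutrophil-like cells, removal of doublets at the expected rate 0 and removal of large cells 6. With cluster 5 added, 1 gene, Ccl4, was called in macrophage and monocyte-like cells. An estimated correlation left 0 lists in each of the 4 comparisons. In CD8 T-like cells the MHC-I list lost its call under RLE, with no filter and with doublets kept, the interferon gamma list with no filter and with doublets kept, and the ribosomal list with doublets kept. The macrophage unfolded protein response list lost its call with doublets kept, and the whole-tumour mesenchymal list with no filter. Lists gained with doublets kept were MHC-II, effector and mesenchymal in the main population, one-carbon in macrophage and monocyte-like cells, and S phase and monocyte genes in CD8 T-like cells. With no filter angiogenesis was gained in the main population, and S phase, mitochondrially encoded and monocyte genes in CD8 T-like cells. Without sedentary 2 and exercise 5 the counts were 1 in the main population, 0 in CD8 T-like, 0 in neutrophil-like, 3 in NK-like and 4 in Treg-like cells, and 1 share, that of neutrophil-like cells, passed. Of the passing lists, 8 of 11, 5 of 8, 10 of 14 and 4 of 10 kept their call in the 4 main comparisons. Hypoxia (-0.072), glycolysis (0.0068) and cholesterol synthesis (0.023) were among those lost in CD8 T-like cells. Cholesterol synthesis was newly called lower in the whole tumour (-0.31) and main population (-0.32).

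Without each library in turn, called genes ranged from 0 to 0 in the whole tumour, main population and mast-like cells, 0 to 1 in macrophage and monocyte-like cells, 0 to 4 in CD8 T-like cells, 0 to 2 in cluster 5, 0 to 9 in dendritic-like, 0 to 17 in neutrophil-like, 1 to 4 in NK-like and 1 to 3 in Treg-like cells. Passing lists ranged from 9 to 15, 5 to 12, 9 to 16 and 3 to 15 in the 4 main comparisons, and passing shares from 0 to 1.

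The type I interferon list reversed most. Without both sedentary 2 and exercise 5 its median was 0.37 in the whole tumour, 0.37 in the main population, 0.33 in macrophage and monocyte-like and 0.014 in CD8 T-like cells. Without 1 library it ranged from -0.20 to 0.20 (0.20 without sedentary 2, 0.094 without exercise 5) in the whole tumour, -0.21 to 0.25 (without exercise 5) in the main population and -0.33 to 0.091 (without sedentary 2, 0.039 without exercise 5) in macrophage and monocyte-like cells. In these last cells without both libraries, the S phase (-0.11), mitochondrially encoded (-0.18), mesenchymal (0.14) and cholesterol synthesis (-0.20) medians reversed. There S phase ranged from -0.16 (without sedentary 2) to 0.33, mitochondrially encoded genes from -0.13 (without exercise 5) to 0.13 and monocyte genes from -0.78 to 0.10 (without sedentary 2).

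In the whole tumour the effector list ranged from -0.32 (without exercise 5; -0.20 without sedentary 3) to 0.35, exhaustion from -0.32 (without exercise 5) to 0.32, G2/M from -0.013 (without exercise 6) to 0.21, the unfolded protein response from -0.080 (without sedentary 1) to 0.16 and monocyte genes from -0.75 to 0.46 (without sedentary 2). In the main population G2/M ranged from 0.011 (without exercise 6, with the test pointing down) to 0.24 and the unfolded protein response from -0.065 (without sedentary 1) to 0.17. In CD8 T-like cells interferon gamma ranged from -0.35 to 0.017 (without sedentary 2), G2/M from -0.13 (without exercise 8) to 0.32, and mesenchymal and heat shock from -0.23 and -0.16 (without sedentary 1) to 0.10 and 0.085. Outside the fits that left out 1 library, 473 of 573 list medians, 296 of 314 named gene values and 135 of 136 shares kept their side of the threshold. Among these, 32 list medians, 2 gene values and 15 shares that did not pass changed sign. In the fits that left out 1 library, 505 of 654 list medians, 569 of 576 named gene values and 107 of 108 shares kept their side. Of those kept, 91 list medians, 76 gene values and 19 shares that did not pass changed sign. Another 20 list results reversed, so directions turned more often when 1 library was left out.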

Other observations

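Of the tests in this part, all splits of the libraries, the fits without both sedentary 2 and exercise 5, and those without large neutrophil-like cells were chosen after the results were seen. The 3 relations over the 6 libraries were chosen before.

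Interferon-induced genes followed individual libraries. The type I interferon list, which includes Ifit3, Isg15 and Rsad2, had scores of 4.87, 5.34 and 5.01 in sedentary 1, 2 and 3 and 4.34, 5.42 and 5.21 in exercise 5, 6 and 8 in the main non-immune population. With all libraries the median log2 fold change was -0.05 in the whole tumour, -0.01 in the main population, -0.14 in macrophage and monocyte-like cells and -0.33 in CD8 T-like cells. Without sedentary 2 and exercise 5, the libraries with the lowest median UMIs per cell, the medians were 0.37 (camera adjusted p = 4.24e-19), 0.37 (6.51e-18), 0.33 (4.17e-16) and 0.01 (0.429). Over all alternatives the adjusted p in the whole tumour ranged from 4.24e-19 to 0.986. Whether type I interferon genes differ between the groups may therefore depend on those libraries, and 2 libraries per group remain when they are left out. The interferon gamma list had a median of 0.34 (adjusted p = 4.6e-12) in the whole tumour and 0.31 (9.73e-10) in the main population without the same pair, 0.33 (6.48e-08) in macrophage and monocyte-like cells and -0.039 (0.515) in CD8 T-like cells. Over all alternatives its adjusted p in the whole tumour ranged from 2.62e-13 to 0.864. These calls rest on the preset correlation of camera, and with all libraries no list passed once the correlation was estimated.

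Without the cells with over 5 times the median UMIs, 6 genes passed in neutrophil-like cells, named here after their values were seen. Clec5a, a myeloid activation receptor gene, rose from 58.6 ± 26.99 to 284.9 ± 45.9 CPM (log2 fold change 1.94, edgeR adjusted p = 0.0162), and Gbp2, an interferon-induced GTPase gene, from 605.5 ± 153 to 1696 ± 591 CPM (1.27, adjusted p = 0.0471). Retnlg, a gene of mature neutrophils, fell from 2561 ± 608 to 920.2 ± 290.3 CPM (-1.57, adjusted p = 0.0162). Wfdc17 (-1.86, adjusted p = 0.0281), Stfa1 (-2.58, adjusted p = 0.0338) and Coq10b (-1.80, adjusted p = 0.0471) fell too. Some counts were low: Stfa1 had 35, 49 and 8 UMIs in sedentary and 5, 0 and 3 in exercise libraries. Coq10b had 82, 74 and 24 against 28, 2 and 1 UMIs, and Clec5a 19, 19 and 3 against 57, 12 and 15. The lowest library counts of Wfdc17, Retnlg and Gbp2 were 15, 21 and 51 UMIs. Exercise 6 held 40 cells of the class. With all cells of the class kept and the settings of the report, their adjusted p ranged from 0.0731 to 0.239, so none of the 6 passed. With all cells and other settings Clec5a, Wfdc17, Stfa1 and Gbp2 each passed in at least 1, and Retnlg and Coq10b in none.

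Relations between CD8 T-like cells and the tumour were weak over the 6 libraries. The share of CD8 T-like cells and the interferon gamma score of the main population had r = 0.171 (exact permutation p = 0.738, adjusted 0.831) and rho = 0.486 (exact p = 0.356, adjusted 0.628), with r = 0.213 without sedentary 3 and exercise 5, the farthest pair. The same share and the MHC-I score had r = 0.106 (exact permutation p = 0.831, adjusted 0.831) and rho = 0.143 (exact p = 0.803, adjusted 0.803), with r = -0.389 without the same pair. The hypoxia score and the macrophage and monocyte-like share had r = 0.618 (exact permutation p = 0.208, adjusted 0.624) and rho = 0.429 (exact p = 0.419, adjusted 0.628), with r = 0.938 without sedentary 3 and exercise 6. All tests were two-sided, and 6 libraries are too few to tell these relations from none.

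The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The number of splits with as many called genes as the real one, the real one included, was 10 in the whole tumour (0 genes, highest other split 0), 10 in the main population (0, 0), 10 in macrophage and monocyte-like cells (0, 34), 7 in CD8 T-like cells (1, 4), 10 in cluster 5 (0, 2), 10 in dendritic-like (0, 7), 10 in mast-like (0, 13), 2 in neutrophil-like (1, 9), 6 in NK-like (1, 3) and 4 in Treg-like cells (1, 3). For lists passing camera it was 8 in the whole tumour (11 lists, highest other split 16), 10 in the main population (8, 15), 4 in macrophage and monocyte-like cells (14, 16) and 6 in CD8 T-like cells (10, 13). Where the real split called 0 genes, every split has at least as many, so the 10 there was fixed in advance and carries no information. The macrophage split with 34 genes set sedentary 1, exercise 6 and exercise 8 against sedentary 2, sedentary 3 and exercise 5. It was picked for its count, and a structure of these libraries other than the groups is possible but was not tested. The same split separated the shares of cluster 7 in the main population (8.45%, 0.884% and 5.86% against 19.3%, 12.9% and 13.6%). It also separated those of macrophage cluster 13 (8.204%, 5.50% and 13.5% against 31.8%, 26.7% and 26.8%). The hypoxia scores of the main population were separated by it too, while by group they overlapped. Cluster 13 is part of the class that gave the 34 genes, and Ero1l and Slc2a1 of the hypoxia list are among the leading genes of cluster 7. These separations are therefore not independent of each other or of the choice of split. A value separates a given split by chance with a probability of 0.10. The neutrophil-like split with 9 genes and the dendritic-like split with 7 set sedentary 1, sedentary 3 and exercise 8 against the rest. The mast-like split with 13 set sedentary 1, sedentary 2 and exercise 5 against the rest.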
